A study of Mus musculus with 28 samples.

How the data were processed

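Single-cell RNA was measured in spleen cells of C57BL/6 mice aged 12 to 15 weeks, in 28 samples. Each sample was a set of wells sorted by flow cytometry and sequenced as 3' tags. Suspensions were enriched on magnetic beads for CD11c, a surface protein of dendritic cells, except for the samples sorted on CD19 and on NK1.1 or Gr1, per the labels' protocols. The groups, taken from the labels, were CD11c+ cells of untreated mice (5 samples), of mice injected with PBS (8 samples) and of mice injected with 1 µg of lipopolysaccharide (LPS, 8 samples), the last 2 groups collected 2 hours after injection. The other 7 samples were sorted on further surface markers. The deposited well table split 2 of them into a pair of gates each, which gave 9 gates. In that table all PBS samples came from 1 mouse and all LPS samples from 1 mouse, and no mouse was given for the other samples. Replicates of PBS and of LPS were therefore libraries of the same animal. Every p-value measured the spread between libraries, and for PBS and LPS none measured that between animals. Whether the untreated libraries came from 1 mouse or several is not known.

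The values analysed were the counts deposited by the authors: molecules per gene and well, counted as distinct molecular tags (UMIs) after the authors' filtering, per the file headers and the series design. Reads had been mapped to mouse build mm9, per the submitters' processing notes. The aligner, the gene models and the filter settings were not given in the sources used here. The values were whole numbers from 0 to 873 in 4590 wells. The well table listed 4598 wells, of which 8 had no column of counts. Of 20190 table entries, 83 were spike-in controls, which held 13.2% of all counts and stayed out of library sizes and tests. Of the other 20107, 539 carried several gene names joined together and are given under the joined name (Ccl4_ScyA4). Members of gene families with near-identical copies, such as the ribosomal protein, immunoglobulin, histocompatibility and kallikrein genes, may share reads, and their values are uncertain to that extent.

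Wells sorted with 1 cell (4468) were kept when they held at least 200 UMIs of genes, which left 3918. No doublet caller was run, since each well was sorted with a single cell. Wells sorted with 0 cells (44) served as background. In the PBS and LPS libraries the 16 such wells held a median of 16.0 UMIs (3 to 44) beside 533.5 in wells with 1 cell, and none reached 200. In the untreated libraries the 19 such wells held a median of 502 UMIs (0 to 1673) beside 1079, and 15 reached 200. Of these 19, 12 belonged to replicate 2 (median 787.5), and the 7 wells of the other libraries held a median of 88 (0 to 453), 3 of them reaching 200, so part of the UMIs of an untreated well can be RNA from other wells. The 78 wells sorted with more than 1 cell were not used in comparisons.

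Cell classes were built from the untreated and PBS cells only. Features were the 500 most variable genes with at least 30 UMIs, without spike-ins, ribosomal and mitochondrial genes and without 13 response lists fixed before the data were examined. Pearson residuals (theta 10, limited to 8) were reduced to 15 principal components, joined in a graph of 15 shared nearest neighbours, and clustered by the Leiden method at resolution 0.35 (leidenalg 0.10.2, python-igraph 0.11.9). A cluster took the name of the marker list with the most detected members, at least 3, where a detected member had at least 10 UMIs and a level at least 1.5 times that of the other clusters. A second list was added to the name when its number of detected members was at least 0.75 of the first. The 14 marker lists were also fixed before the data were examined, and 162 of their 173 genes were in the table. Every kept cell of all groups was then assigned to the class with the highest Poisson likelihood, with profiles smoothed by 5 UMIs. This returned 95.97% of the untreated and PBS cells to their own cluster. A class is written as, for example, "B-like", since it rests on RNA alone.

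UMIs were summed over the cells of each library, or of each library and class where at least 5 cells were present, and a class was tested with at least 4 such sums per group. Genes were filtered with filterByExpr, scaled by TMM over the genes kept, and tested with edgeR 4.0.16 (glmQLFit, glmQLFTest) under R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method within each fit, with a threshold of 0.05, and "rose" and "fell" are used only of genes past it. Filtering came before scaling because the sums of small classes are mostly zeros. Levels are UMIs per 10000, TMM scaled, as mean ± SD over libraries. Log2 fold changes carry their standard error. Where one group had no count, a fold is given as a lower bound against 3 counts over the group. With 1 to 3 counts the ratio is given with its exact 95% interval. Differences of the LPS response between classes were tested in 1 fit of all class sums with terms for the library, the class and the class by LPS, each class against the CD8- cDC-like class.

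The 13 response lists (299 of 305 genes in the table) were tested with camera (limma 3.58.1) at its preset correlation of 0.01, and again with an estimated correlation. For each list the number of members past the threshold is given over all genes tested, and adjusted over the list alone where the number differed. Shares of cells per class were compared by exact two-sided permutation tests of the difference of mean percentages, adjusted over the 8 classes. The smallest unadjusted p they can give was 0.000155 for LPS against PBS (12870 splits) and 0.000777 for PBS against untreated (1287 splits). Sorted gates had 1 library each and no test. Their shares have exact Clopper-Pearson intervals and their levels exact Poisson intervals, both at 95%, which cover counting error only. Shares of cells with a Cxcl10 UMI are also given after every cell was thinned to 200 UMIs at random.

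The genes named were fixed by rule before the data were examined. For LPS against PBS in all cells these were the 15 largest increases and 10 largest decreases past the threshold. The rule took 6 and 3 for each class and 8 and 8 for PBS against untreated. For differences between classes it took the 5 genes with the smallest adjusted p. For the lists it took up to 4 members with the smallest adjusted p and the member with the largest mean level that did not pass. For gates it took the 6 genes with the largest ratio to the mean of the other gates (0.5 added to both) among genes with at least 50 UMIs, and the genes of the sort markers, of which Ly6g was not in the table. Genes named outside this rule are said to be chosen after their values were seen.

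The procedure was tested on simulated data drawn from the means and library sizes of the real libraries, with 66 or 67 genes changed by each fold where all cells were tested and 46 or 47 in CD8- cDC-like cells. For LPS against PBS in all cells (1913 genes), 38.8% of genes changed 1.5-fold, 70.1% of those changed 2-fold and 77.3% of those changed 4-fold were recovered. For PBS against untreated (1701 genes) the shares were 8.96%, 49.3% and 81.8%, and in CD8- cDC-like cells (554 genes) 51.1%, 84.8% and 76.1%. Recovery of genes changed 1.5-fold varied in the other classes, from 0 of 6 in monocyte-like cells to 54.5% in CD8+ cDC-like cells. It was 2.63% to 21.1% of such genes for the differences between classes. Called genes that had not been changed were 8 of 132 in all cells, 4 of 102 in CD8- cDC-like cells, 5 of 98 for PBS against untreated, 3 of 26 in CD8+ cDC-like cells, and 8 of 70 and 7 of 65 for the differences of B-like and mature dendritic-like cells, so up to about 11% of calls in the last 3.

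Alternatives tried were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, cell minimums of 100 and 400 UMIs, each library left out in turn, resolutions of 0.2 and 0.7, response lists kept among the features, 10 cells per class sum, and the sequencing batch as a block. Chosen after seeing the data were library totals with no scaling factor, the block within classes, classes built without the genes called within any class, and leaving out libraries in the PBS against untreated shares. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.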

Results

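The data were UMI counts of single spleen cells, enriched on CD11c and collected from untreated mice or 2 hours after injection of PBS or of 1 µg LPS. After wells with fewer than 200 UMIs were left out, 678 of 701 untreated cells, 1283 of 1528 PBS cells and 1325 of 1528 LPS cells remained. Libraries kept 36 to 186 cells in 5 untreated libraries, 140 to 180 in 8 PBS libraries and 141 to 185 in 8 LPS libraries. Median UMIs per kept cell ranged over libraries from 703 to 1493 (433.5 to 871 genes) in untreated, 456 to 750.5 (332 to 468 genes) in PBS and 553.5 to 857 (391 to 539 genes) in LPS. UMIs kept per library were 47439 to 296730, 79985 to 137071 and 104691 to 166887. Cells of 9 sorted gates numbered 39 to 92 per gate, with medians of 364 to 1752 UMIs. All PBS libraries came from 1 mouse and all LPS libraries from 1 mouse, so the p-values below measure the spread between libraries only.

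CD11c enrichment did not leave dendritic cells alone: the untreated and PBS cells held 8 classes, of which 4 were not dendritic. The largest class, 837 cells, was named for CD8-negative conventional dendritic cells (CD8- cDC) and was led by Ifitm1, Ffar2, Cyp4f16 and S100a4, with 4 of 13 markers detected (Clec4a4, Dtx1, Cd209a and Tmem176b). CD8+ cDC-like cells (117) expressed Naaa, Cst3, Ppt1 and Irf8, with 15 of 17 markers detected. Plasmacytoid (pDC-like) cells (56) expressed Klk1, Siglech, Cox6a2 and Ctsl, with 10 of 15. Mature or migratory dendritic-like cells (171) expressed Ccr7, Fscn1, Ccl22 and Cacnb3, with 8 of 9. The other classes were B-like (376 cells; Cd79a, Cd79b, Cd19 and Ms4a1; 13 of 15 markers), NK/T-like (154; Xcl1, Gzma, Nkg7 and Tcra; 11 of 14 NK and 10 of 14 T markers), monocyte-like (128; Ace, Lyz2, Fcgr4 and Cd300e; 11 of 15) and macrophage-like (122; Fcna, C1qc, Hmox1 and Slc40a1; 14 of 16).

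In untreated mice CD8- cDC-like cells were the most frequent CD11c+ class, and B-like cells came next. CD8- cDC-like cells made up 51.9 ± 18.0% of cells per library (range 38.0 to 83.3%, n = 5 libraries, 318 cells). The highest share was that of replicate 2, which kept 36 cells. Its wells sorted with no cell held a median of 787.5 UMIs, beside 1035.5 in its wells of 1 cell. With 1 library left out the mean ranged from 44.0 to 55.3%. B-like cells made up 13.0 ± 8.56% (0 to 22.8%, 98 cells) and monocyte-like cells 8.95 ± 4.60% (2.78 to 13.3%, 73 cells). NK/T-like cells followed with 7.22 ± 2.57% (4.35 to 11.0%, 54 cells), CD8+ cDC-like with 7.01 ± 3.88% (2.78 to 11.0%, 53 cells) and mature dendritic-like cells with 6.10 ± 2.69% (2.78 to 10.2%, 47 cells). Macrophage-like cells were 4.36 ± 4.27% (1.66 to 12.0%, 25 cells) and pDC-like cells 1.52 ± 1.69% (0 to 4.35%, 10 cells). With 1 library left out these 2 means ranged from 2.46 to 5.04% and from 0.817 to 1.90%.

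LPS changed the RNA of the CD11c+ compartment broadly within 2 hours. Genes of the interferon response were among the largest increases: Ifit3, Ifit2, Ifit1, Rsad2, Mx2, Oasl1 and the chemokines Cxcl10 and Cxcl11. The early activation gene Cd69, the interleukin-1 antagonist Il1rn and the metallothionein Mt2 rose with them. The iron exporter Slc40a1, the kinase Mapk14 and the interleukin Il16 fell. Bacterial LPS is sensed by TLR4, whose TRIF arm leads to type I interferon, a well described route to these genes. Of 1896 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 477 rose and 450 fell (8 against 8 libraries). For 371 of these 927 genes every LPS library lay beyond every PBS library, which held for each gene named in the next paragraph.

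Ifit3 rose from 0.481 ± 0.316 to 29.6 ± 5.20 UMIs per 10000 (log2 fold change 5.85 ± 0.24, adjusted p = 9.1e-15). I830012O16Rik, which lies beside the Ifit genes, rose by 5.91 ± 0.32 (4.0e-13), Ifit2 by 5.52 ± 0.28 (1.3e-13), Ifit1 by 4.95 ± 0.36 (5.3e-11) and Rsad2 by 5.11 ± 0.30 (1.7e-12). Cxcl10 rose from 3.10 ± 3.59 to 124 ± 7.58 (5.25 ± 0.38, 5.0e-11), and Cxcl11 went from 2 counts to 197 (ratio 76.6, interval 20.9 to 637; 3.7e-10). Cd69 rose from 0.142 ± 0.111 to 6.07 ± 1.19 (5.22 ± 0.27, 2.3e-13). Increases were also measured for Il1rn (5.64 ± 0.43, 1.2e-10), Mt2 (5.40 ± 0.40, 6.9e-11), Ifi205 (5.24 ± 0.47, 1.7e-09), Mx2 (4.71 ± 0.32, 1.4e-11), Mnda (4.58 ± 0.35, 1.2e-10), Serpina3f (4.46 ± 0.26, 1.3e-12) and Oasl1 (4.41 ± 0.32, 4.9e-11). PBS replicate 4 held more of these RNAs than the other PBS libraries. Without it the changes were Mt2 6.79, I830012O16Rik 6.81, Ifit2 6.21, Ifit1 6.20, Cxcl10 6.08, Rsad2 5.94, Mx2 5.57 and Oasl1 5.27. Slc40a1 fell from 2.35 ± 0.846 to 0.169 ± 0.0956 (-3.73 ± 0.33, 1.4e-09), Mapk14 from 3.07 ± 0.834 to 0.463 ± 0.190 (-2.69 ± 0.23, 9.3e-10) and Asb2 from 6.08 ± 0.916 to 1.09 ± 0.429 (-2.47 ± 0.19, 1.6e-10). The other largest decreases were Bmyc (-2.60 ± 0.24, 3.6e-09), Susd3 (-2.42 ± 0.31, 4.0e-07), Il16 (-2.40 ± 0.19, 1.6e-10), Fam105a (-2.32 ± 0.25, 2.6e-08), Slc46a3 (-2.31 ± 0.18, 1.0e-10), Scarb1 (-2.17 ± 0.30, 1.8e-06) and Mical1 (-2.14 ± 0.24, 8.2e-08).

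**Figure D1:**
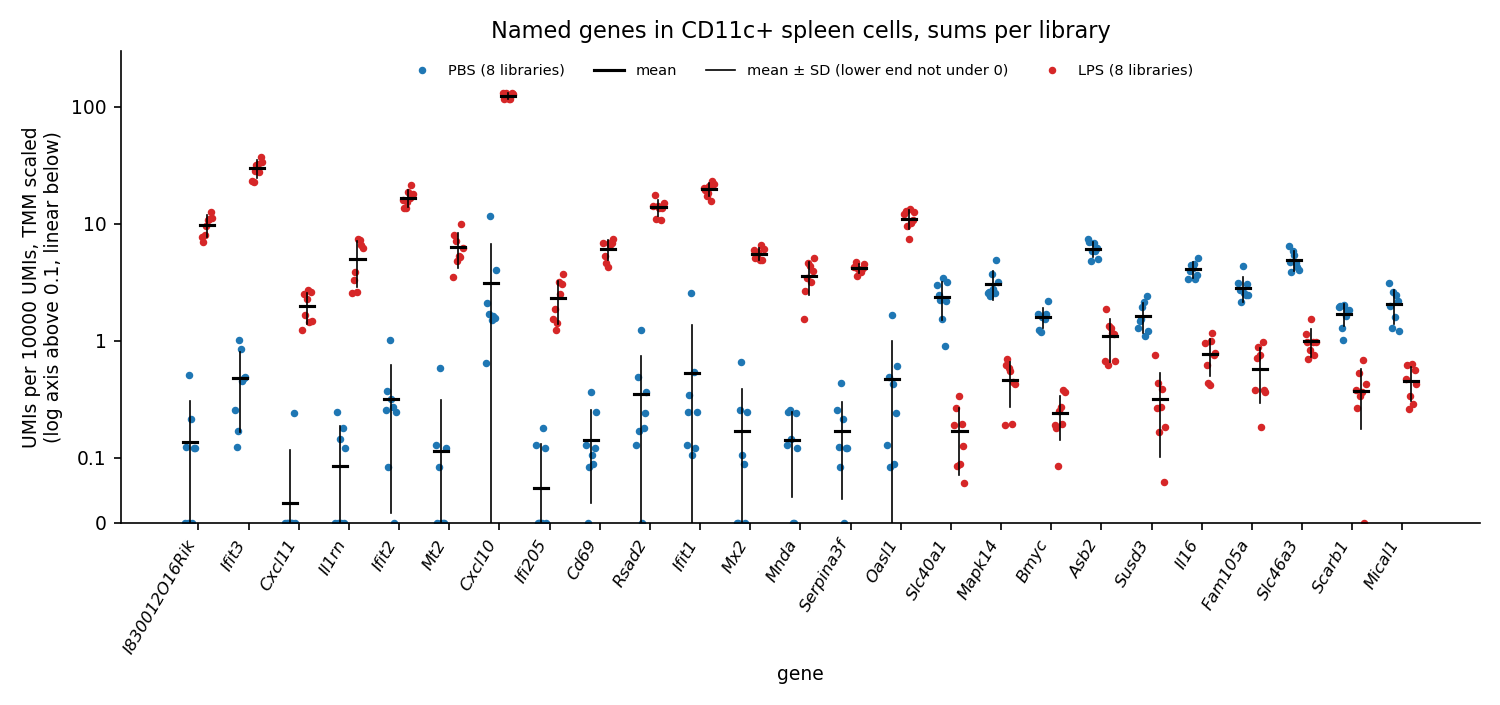
UMIs per 10000 of the genes with the largest changes between PBS and LPS in all CD11c+ cells, 1 point per library (n = 8 and 8) with mean ± SD, on an axis that is logarithmic above 0.1 and linear below. The PBS and LPS points of every gene are apart.

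Interferon programs rose as a whole. Of the type I interferon list, 38 of 38 genes tested rose (adjusted p over the lists, by camera, 2.9e-48), among them Irf7 (2.78 to 24.9; 3.15 ± 0.15), Mx1 (4.12 ± 0.20) and Usp18 (4.07 ± 0.20). All 10 tested genes associated with interferon-gamma rose too (1.2e-13), with Igtp (3.66 ± 0.16), Irgm1 (4.07 ± 0.25), Socs1 (3.86 ± 0.27) and Iigp1 (3.98 ± 0.30). Cytokine and chemokine genes rose in 7 of 8 (2.5e-05), including Ccl4_ScyA4 (1.13 to 16.9; 3.93 ± 0.32) and Il15 (3.19 ± 0.30), whereas Cxcl16 had -0.28 ± 0.20 (adjusted p = 0.249). Among NF-kB targets 15 of 17 rose (1.6e-06), with Bcl2a1a (2.59 ± 0.24), Cflar (2.26 ± 0.22), Marcksl1 (1.78 ± 0.15) and Birc3 (1.52 ± 0.15), and Nfkb1 had -0.18 ± 0.14 (0.290). Costimulation and maturation genes rose in 7 of 9 (7.1e-07): Cd69, Cd86 (3.64 ± 0.35), Cd274 (2.69 ± 0.23) and Cd40 (2.53 to 13.2; 2.37 ± 0.17), with Relb at 0.03 ± 0.14 (0.875).

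Antigen presentation split by class of molecule in these sums over all cells, whose mixture of classes shifted too. MHC class I genes rose in 11 of 15 and fell in none (camera 0.0129), with Nlrc5 (1.94 ± 0.25), Tapbp (1.75 ± 0.23), B2m (6.65 to 39.8; 2.58 ± 0.36) and H2-Q7 (0.81 ± 0.11), and H2-D1 had 0.16 ± 0.10 (0.201). B2m and Tapbp were lower in PBS than in untreated libraries, where B2m was 77.3 ± 25.2, so the rise of B2m after LPS started from a low PBS level and ended below the untreated one. MHC class II genes fell in 9 of 11 (camera 0.00549, adjusted p = 0.143 with an estimated correlation): Cd74 from 438 to 309 (-0.50 ± 0.06), H2-DMa from 14.5 to 6.76 (-1.10 ± 0.13), H2-Aa (-0.42 ± 0.07) and H2-Ab1 (-0.44 ± 0.08), with Ctss at -0.07 ± 0.11 (0.616). Within single classes Cd74 and H2-Ab1 each fell in 3 of 8, H2-Aa in 2 of 8 and H2-DMa in 2 of 4 tested. Ribosomal protein genes fell in 13 of 32 and rose in 1 (camera 0.0394, adjusted p = 0.557 with an estimated correlation). Rps5 (-0.42 ± 0.10), Rplp1 (-0.34 ± 0.09) and Rpl27a (-0.99 ± 0.26) fell while Rpl23 rose from 9.99 to 34.2 (1.78 ± 0.28).

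Small lists moved gene by gene. Myd88 rose from 2.08 to 5.40 (1.36 ± 0.15), the only 1 of 3 TLR4 receptor and adaptor genes to do so (camera 0.552), and Irf5 had -0.05 ± 0.17 (0.840). Immediate early genes rose in 4 of 7 and fell in 2 (0.254), with Atf3 (3.41 ± 0.27), Klf6 (1.80 ± 0.22) and Dusp1 (1.19 ± 0.25) against Klf2 (-1.36 ± 0.19), and Zfp36 had 0.43 ± 0.26 (0.168). Glycolysis genes fell in 3 of 4 (0.254): Gpi1 (-0.73 ± 0.18), Aldoa (-0.43 ± 0.16) and Pkm2 (-0.43 ± 0.17), with Ldha at -0.04 ± 0.17. Proliferation genes fell in 2 of 3 (3 adjusted over the list alone; camera 0.228), Pcna by -0.85 ± 0.19 and Tuba1b by -0.41 ± 0.16, and Mcm5 had -0.75 ± 0.34 (0.0717). The only glucocorticoid target tested, Txnip, fell (-0.50 ± 0.18, 0.0272). With no filter on low counts the median of all genes moved up by 0.18, only 3 class II genes, 3 ribosomal genes and 0 glycolysis genes fell, and Txnip did not pass.

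Markers of cell types moved in the same sums, and some of them also within classes. Among pDC markers 7 of 8 rose (Siglech, Klk1, Cox6a2, Upb1, Ly6d, Cd300c and Mpeg1), as did 4 of 4 NK markers (Klrk1, Gzma, Nkg7 and Ccl5), 4 of 6 markers of mature dendritic cells (Ccr7, Fscn1, Socs2 and Il4i1) and 6 of 8 monocyte markers (Lyz2, Ly6c2, Cd14, Ms4a6c, Ms4a4c and Cebpb, with Csf1r lower). B markers fell in 5 of 6 (Cd79a, Cd79b, Cd19, Cd22 and Faim3) and macrophage markers in 7 of 10 (C1qa, C1qb, C1qc, Slc40a1, Emr1, Apoe and Fcna), while Vcam1 and Spic rose. Markers of CD8- cDC went both ways in 8 tested (Cd4, Clec4a1 and Cd209a higher; Sirpa, Dtx1, Ltb and Tmem176b lower). Of 6 CD8+ cDC markers Ifi205 rose and Naaa, Wdfy4 and Cd24a fell. Single markers that rose were Xbp1 of plasma cells (1 tested), Tcf7 of T cells (2 tested) and Car2 of erythroid cells (1 tested). No neutrophil, basophil or mast cell, or platelet marker was tested.

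In CD8- cDC-like cells, the most frequent class, Ifit3, Ifit2, Rsad2, Mx2 and Cxcl10 rose from low levels, and Cd69, Cd40 and Cd274 rose as well. Fam105a, Slc46a3 and Mapk14 fell. Of 556 genes tested, 168 rose and 124 fell (482 PBS and 296 LPS cells, 8 against 8 libraries). Ifit3 rose from 0.397 to 47.5 ± 6.50 (6.59 ± 0.30, 8.0e-15), Cxcl10 from 2.66 ± 2.93 to 184 ± 16.6 (5.94 ± 0.33, 1.7e-13) and Mx2 from 3 counts to 186 (ratio 75.3, interval 25.4 to 369), beside I830012O16Rik (6.52 ± 0.33), Ifit2 (6.03 ± 0.28) and Rsad2 (5.95 ± 0.30). Fam105a fell from 4.09 to 0.430 (-3.12 ± 0.30, 3.7e-09), Slc46a3 from 7.10 to 0.809 (-2.98 ± 0.29) and Mapk14 from 4.61 to 0.607 (-2.91 ± 0.34). For all 9 genes every LPS library lay beyond every PBS library, and so it did in the classes that follow for each gene picked by size of change, unless a smaller number of libraries is given.

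The lists in CD8- cDC-like cells followed those of all cells. Interferon genes rose in 28 of 28 (camera 3.3e-26) and interferon-gamma genes in 4 of 4 (0.000318), with Gbp2 (4.36 ± 0.31), Igtp (3.92 ± 0.28) and Irf1 (1.30 ± 0.26). Cytokine genes rose in 2 of 2 (0.0119; Ccl4_ScyA4 4.48 ± 0.43). NF-kB targets rose in 9 of 12 and fell in 1 (0.0379, adjusted p = 0.355 with an estimated correlation; Gadd45b 2.25 ± 0.22, Marcksl1 2.13 ± 0.19), and Nfkbie had 0.19 ± 0.25 (0.539). Costimulation genes rose in 4 of 6 (0.0251, adjusted p = 0.118 with an estimated correlation): Cd69 (5.14 ± 0.38), Cd40 (2.76 ± 0.20), Cd274 (2.49 ± 0.27) and Icam1 (1.00 ± 0.27), with Relb at 0.19 ± 0.20 (0.438). MHC class II genes fell in 6 of 9 (7 over the list alone; 0.0379, adjusted p = 0.342 with an estimated correlation; H2-DMa -1.11 ± 0.15, Cd74 -0.39 ± 0.07). Ribosomal genes fell in 10 of 26 with Rpl23 higher (0.0379, adjusted p = 0.490 with an estimated correlation; Rplp1 -0.39 ± 0.10). Class I genes rose in 9 of 12 (0.263; Tapbp 1.87 ± 0.26, B2m 2.58 ± 0.37), Myd88 rose (1.54 ± 0.23), Gpi1 and Pkm2 fell, and Txnip fell (-1.20 ± 0.25). Markers of mature dendritic cells, Ccr7, Fscn1 and Il4i1, rose within this class (3 of 3 tested), as did the monocyte markers Ms4a6c and Ms4a4c, while Sirpa and Ltb fell.

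Mature dendritic-like cells gained interferon genes, while maturation genes went both ways. Rsad2, Isg20, Ifit3 and Cxcl10 rose, and of the costimulation genes Cd40 rose while Cd83 and Relb fell. These cells carry high Ccr7 before any stimulus, as migrating dendritic cells do. Of 161 genes 39 rose and 24 fell (133 PBS and 231 LPS cells, 8 against 8 libraries). Isg20 went from 1 count to 269 (ratio 104, interval 18.5 to 4123) and Rsad2 from 2 to 373 (ratio 72.1, interval 19.8 to 598). Cxcl10 rose from 3.08 to 136 ± 33.8 (5.20 ± 0.37, 4.7e-11), with Ifit3 (5.06 ± 0.34), Ifit2 (4.97 ± 0.50) and Ifit1 (4.64 ± 0.40). The decreases were smaller: Ostf1 (-1.21 ± 0.25, 0.000390; 4 of 8 LPS libraries below all PBS), Cxcl16 from 13.3 to 5.89 (-1.13 ± 0.22, 0.000206; 8 of 8) and Ftl1 (-1.0 ± 0.24, 0.00202; 2 of 8). Without the filter on low counts, where the median of all genes moved by 0.49, these 3 did not pass (0.254, 0.342 and 0.304). Interferon genes rose in 15 of 15 (camera 2.5e-18; Ifitm3 3.36 ± 0.27). Both CD8- cDC markers tested, Tmem176a and Tmem176b, fell (median -0.56), and 0 of 3 markers of mature dendritic cells changed. Costimulation genes (0.958) had Cd40 at 1.79 ± 0.24, Cd83 at -0.75 ± 0.21 and Relb at -0.73 ± 0.22, and 1 of 4 NF-kB targets rose (Marcksl1 0.75 ± 0.21). Without called genes among the features this class held 137 LPS cells, and these fits were not repeated there.

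B-like cells gained RNA of interferon genes. Ifit3, Irgm1, Ifi47 and Mx1 rose, and Cd79b, a signalling chain of the B cell receptor, fell. Of 142 genes 29 rose and 14 fell (277 PBS and 204 LPS cells, 8 against 8 libraries), and 13 were called with wells of at least 400 UMIs. Ifit3 rose from 0.486 to 42.7 ± 9.92 (6.27 ± 0.31, 8.0e-13) and I830012O16Rik from 3 counts to 148 (ratio 60.8, interval 20.4 to 298), with Irgm1 (4.23 ± 0.34), Ifi47 (3.96 ± 0.32), Mx1 (3.80 ± 0.44) and Gm4902 (3.71 ± 0.34). Cd79b fell from 54.3 ± 5.32 to 24.3 ± 5.34 (-1.17 ± 0.14, 1.3e-06; 8 of 8 LPS libraries), Gpx1 from 16.6 to 6.52 (-1.29 ± 0.27, 0.000599; 7 of 8; 0.0566 at the lower resolution) and Snord33 by -1.06 ± 0.25 (0.00182; 4 of 8). Cd79b was the only 1 of 6 B markers tested to change. Of other receptor genes, chosen after their values were seen, Cd79a had -0.25 ± 0.26 (0.558) and Igh 0.29 ± 0.26 (0.495), and the immunoglobulin entry M34473 rose (1.19 ± 0.43, 0.0409; 2 of 8). The immunoglobulin entries abParts (0.85 ± 0.39, 0.115) and M13680 (-0.55 ± 0.57, 0.558) did not pass. V00821, a leading gene of the class, fell (-0.54 ± 0.14, 0.00409; 5 of 8). Interferon genes rose in 9 of 9 (camera 5.7e-11). Class II genes fell in 2 of 6 (3 over the list alone; 0.186; H2-Ab1 -0.35 ± 0.12), and class I genes rose in 2 of 6 (0.548; B2m 2.27 ± 0.46, H2-T23 1.08 ± 0.22). B2m was uneven after LPS (29.3 ± 21.1), with 6 of 8 LPS libraries above all PBS.

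NK/T-like cells raised Cxcl10 and interferon genes together with the cytotoxic genes Gzmb, Gzma and Nkg7. Type I interferon is a known activator of NK cell cytotoxicity. Of 119 genes 27 rose and 12 fell (107 PBS and 204 LPS cells, 8 against 8 libraries), and 65 were called without PBS replicate 2. The class mixes NK and T cells, and its leading genes included Tcra, Thy1, Lat and Cd27 after PBS and Ncr1, Prf1 and Gzmb after LPS. Among genes chosen after their values were seen, Cd7 fell (-0.84 ± 0.30, 0.0339; 1 of 8) and TCRA had -0.87 ± 0.50 (0.17). The balance of NK and T cells within the class was not tested. Cxcl10 rose from 3.82 to 155 ± 27.1 (5.27 ± 0.34, 2.8e-11) and Gzmb from 3.43 ± 4.12 to 39.4 ± 14.6 (3.49 ± 0.42, 5.3e-07), with Ifit3 from 3 counts to 267 (ratio 32.6, interval 11.0 to 159), Ifit1 (4.53 ± 0.46), Isg15 (3.46 ± 0.32) and Igtp (3.40 ± 0.36). Crip1 fell by -1.03 ± 0.25 (0.00237; 7 of 8 LPS libraries), LOC100302567 by -1.16 ± 0.32 (0.00679; 2 of 8) and Rnu73a by -1.12 ± 0.33 (0.0108; 2 of 8), and none of these 3 passed without the filter (median of all genes moved by 0.59). Interferon genes rose in 5 of 5 (camera 4.6e-07) and cytokine genes in 2 of 2 (0.000500). Class I genes rose in 4 of 7 (6 over the list alone; 0.148; B2m 2.32 ± 0.51, to 45.6 ± 28.5 after LPS, 6 of 8 LPS libraries). Ribosomal genes fell in 2 of 21 with Rpl23 higher (0.0202, adjusted p = 0.389 with an estimated correlation), and 0 of 4 class II genes changed (0.218).

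Monocyte-like cells raised Cxcl10, the NF-kB inhibitor Nfkbia and the Fc receptor Fcgr4, and lowered the class II genes H2-Aa, H2-Eb1 and Cd74. Of 67 genes 22 rose and 18 fell (70 PBS and 101 LPS cells, 8 against 8 libraries), and 70 were called with wells of at least 400 UMIs. Cxcl10 rose from 2.96 to 120 ± 32.7 (5.37 ± 0.40, 1.6e-10), Nfkbia from 6.36 to 49 (3.06 ± 0.33), B2m from 7.40 to 51.9 (2.86 ± 0.41; 7 of 8 LPS libraries above all PBS), Fcgr4 from 6.11 to 31.1 (2.40 ± 0.37), Srgn from 22.2 to 102 (2.20 ± 0.23) and Ifit1 by 4.51 ± 0.39. H2-Aa fell from 206 to 107 (-0.96 ± 0.27, 0.00719; 4 of 8), Rpl13 by -1.22 ± 0.42 (0.0209; 5 of 8) and Psap by -0.98 ± 0.36 (0.0262; 3 of 8), of which only H2-Aa passed in all settings run. Class II genes fell in 3 of 5 (camera 0.134), class I genes rose in 3 of 3 (0.148) and interferon genes rose in 2 of 2 (0.0134, adjusted p = 0.0588 with an estimated correlation). Ribosomal genes fell in 7 of 15 with Rpl23 higher (0.0249, adjusted p = 0.137 with an estimated correlation). Of cell type markers, Lyz2 of monocytes (0.85) and Apoe of macrophages (1.70) rose and Tmem176b of CD8- cDC fell (-0.79), each the only 1 of its list tested. Without scaling factors the median of all genes in this class moved by -0.30.

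Macrophage-like cells gained the chemokines Ccl4 and Ccl5 and lost Slc40a1, the gene of ferroportin, within the class itself. Red pulp macrophages use ferroportin to release iron, and its loss in inflammation is well known. Of 67 genes 18 rose and 9 fell (93 PBS and 50 LPS cells, 8 against 6 libraries), and 70 were called at the lower resolution. Ccl4_ScyA4 went from 0 counts to 407, at least 221-fold (144 ± 59.6 after LPS), Ccl5 from 4.17 to 139 (4.68 ± 0.42) and Cxcl10 from 2.96 to 178 ± 48.5 (5.40 ± 0.36, 2.6e-10), with Tnfaip2 (4.48 ± 0.45), Marcksl1 (4.31 ± 0.36) and Isg15 (4.10 ± 0.38). Slc40a1 fell from 36.0 ± 20.5 to 3.21 ± 1.30 (-3.29 ± 0.47, 6.3e-06; 6 of 6 LPS libraries), Cd81 by -1.27 ± 0.32 (0.00275; 5 of 6) and Ctsd by -1.14 ± 0.25 (0.000847; 4 of 6). NF-kB targets rose in 2 of 2 (camera 0.0193, adjusted p = 0.117 with an estimated correlation) and cytokine genes in 2 of 2 (0.000184). None of 5 class II genes changed (0.854). The macrophage markers C1qc and Apoe fell and Vcam1 rose, of 8 tested. The median of all genes moved by 0.13 with the other size factors and by -0.18 with none.

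CD8+ cDC-like cells raised Cxcl10, Cxcl9, Serpina3g and Irf7, and lowered Irf8, the factor that specifies this lineage. Of 131 genes 24 rose and 7 fell (72 PBS and 36 LPS cells, 8 against 5 libraries). Cxcl10 rose from 1.65 to 143 ± 37.7 (6.47 ± 0.31, 2.8e-14), Serpina3g from 4.50 to 83.1 (4.27 ± 0.27) and Cxcl9 by 3.76 ± 0.42, with Mx1 (4.54 ± 0.44), Isg15 (4.40 ± 0.37), Parp14 (4.13 ± 0.43) and Irf7 (4.05 ± 0.36). Irf8 fell from 14.3 ± 6.67 to 2.30 ± 1.38 (-2.59 ± 0.44, 4.8e-05; 5 of 5 LPS libraries). Alox5ap fell by -1.33 ± 0.34 (0.00452; 0.0853 without the filter) and Gnai2 by -0.85 ± 0.31 (0.0495; 4 of 5), the latter lost in most other settings. Interferon genes rose in 5 of 5 (camera 8.5e-08), cytokine genes in 2 of 2 (8.7e-07) and NF-kB targets in 2 of 2 (0.0212; Traf1 3.08 ± 0.36, Nfkbia 1.74 ± 0.35). None of 7 class II genes changed (0.795). The median of all genes moved by 0.13 with the other size factors, where 25 genes rose and 2 fell, and by -0.13 with no factor.

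In pDC-like cells Usp18, Ifit2, Irgm1 and Oasl1 rose from next to nothing, and Cd40 rose, while the identity gene Irf8 and the tetherin gene Bst2 stayed near their starting levels. Plasmacytoid cells hold high Irf7 at rest. Of 268 genes 62 rose and 23 fell (42 PBS and 185 LPS cells, 6 against 8 libraries). Usp18 went from 0 counts to 355, at least 19.9-fold (23.5 ± 3.06 after LPS), and Ifit2 from 0 to 174, at least 9.75-fold. Irgm1 went from 1 count to 204 (ratio 34.3, interval 6.08 to 1361), Iigp1 from 1 to 186 (31.3, 5.54 to 1241), AI607873 from 1 to 159 (26.7, 4.73 to 1062) and Oasl1 from 1 to 151 (25.4, 4.49 to 1009). Cxcl10 rose from 2.57 to 46.4 (3.90 ± 0.45, 4.5e-08) and Cd40 by 2.67 ± 0.54, while Irf8 had -0.10 ± 0.24 (0.766) and Bst2 -0.36 ± 0.19 (0.166). Fcrla (-1.37 ± 0.37, 0.00434; 2 of 8 LPS libraries), Mir3091 (-1.35 ± 0.38, 0.00590; 2 of 8) and Snord33 (-1.30 ± 0.40, 0.0109; 6 of 8) fell, though not past the threshold without the filter, where 12 of the 23 decreases had a fold above 0. Interferon genes rose in 12 of 16 (13 over the list alone; camera 1.5e-07) and interferon-gamma genes in 4 of 5 (0.0261, adjusted p = 0.195 with an estimated correlation). Class II genes fell in 2 of 7 (3 over the list alone; 0.0455, adjusted p = 0.195 with an estimated correlation) and ribosomal genes in 3 of 22 (1 over the list alone; 0.00374, adjusted p = 0.195 with an estimated correlation). With no filter the median of all genes in this class moved by 0.89 and that of class II genes, from -0.35 to 0.55, by about as much.

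Cxcl10 and the elongation factor gene Eef1a1 rose in every class. They were the 2 of 28 genes tested in all 8 classes to do so, and none fell in each. After LPS a Cxcl10 UMI was found in 97.3% of CD8- cDC-like, 97.8% of CD8+ cDC-like, 96.6% of macrophage-like, 93.1% of NK/T-like, 90.1% of monocyte-like, 85.3% of mature dendritic-like, 83.2% of pDC-like and 57.4% of B-like cells, against 10.2 to 15.3% after PBS. Thinned to 200 UMIs per cell, the shares were 88.9, 87.0, 86.2, 80.9, 75.2, 68.4, 54.6 and 39.7% after LPS and 0 to 10.1% after PBS. Median depths were 406 to 1221.5 UMIs after LPS and 363 to 1032.5 after PBS. As background, 8 LPS wells sorted with no cell held 1 Cxcl10 UMI in 98 UMIs and 8 such PBS wells 0 in 192, which per well is at most 0.183 of the mean of any class but B-like, and at most 0.582 of the mean of B-like wells. Without PBS replicate 4 the change of Cxcl10 was 6.76 in CD8- cDC-like, 6.64 in mature dendritic-like, 6.14 in NK/T-like, 6.19 in monocyte-like and 6.10 in macrophage-like cells. Eef1a1 rose from 20.9 to 53.3 in all cells (1.35 ± 0.22, 1.6e-05), and by 1.11 ± 0.25 in pDC-like to 2.18 ± 0.30 in macrophage-like cells. Of 647 genes tested in any class, 8 rose in 1 class and fell in another (Acp5, Apoe, Cyba, H2-Q7, Ifi30, Itm2b, Lsp1 and Ptprc).

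**Figure D2:**
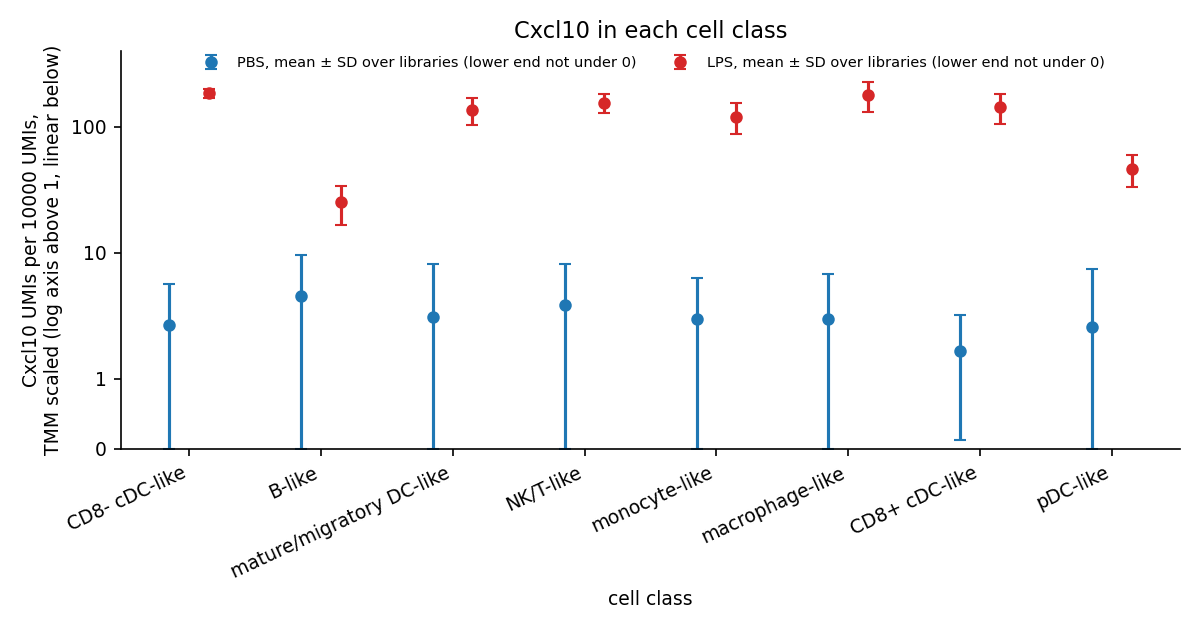
Cxcl10 in UMIs per 10000 for each class after PBS and after LPS, mean ± SD over libraries, on an axis that is logarithmic above 1 and linear below. The LPS level was lowest in B-like and pDC-like cells.

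The response differed between classes for 21 to 45 of the 532 genes tested against the CD8- cDC-like response. B-like cells responded less in Cxcl10 (difference of log2 fold changes -3.67 ± 0.37, adjusted p = 4.3e-15; 5.64 to 26.0 against 2.97 to 182), Srgn (-1.90 ± 0.22), Ccr7 (-2.52 ± 0.47) and Cd40 (-1.94 ± 0.44), and V00821 had 1.27 ± 0.28. In mature dendritic-like cells Gadd45b (-2.19 ± 0.30, 7.0e-09; 27.7 to 24.4 against 2.15 to 9.18), Ccr7 (-1.80 ± 0.30), Fscn1 (-1.65 ± 0.28) and Ccl5 (-1.73 ± 0.29) responded less. Ccr7, Fscn1 and Gadd45b are among the leading genes of this class. Where cells are placed by such genes, their level in the class can move less. Gadd45b, a response list gene, was not among the features that placed cells. Gm2a went from 4.77 to 9.47 there and from 36.6 to 18.4 in CD8- cDC-like cells (1.94 ± 0.30). NK/T-like cells differed in Cyba (10.7 to 24.5 against 23.0 to 15.1; 1.69 ± 0.26, 4.3e-07), Irf8 (1.28 to 9.01 against 1.25 to 0.783; 2.95 ± 0.64), Srgn (-1.31 ± 0.24), Ccl5 (-1.58 ± 0.29) and Ccr7 (-2.81 ± 0.59). Sfpi1, the gene of the PU.1 factor, went from 13.7 to 3.49 in CD8- cDC-like cells but from 10.7 to 11.4 in monocyte-like (1.93 ± 0.33) and from 8.33 to 12.7 in macrophage-like cells (2.57 ± 0.41, 1.3e-06). The response of Nfkbia was larger in both (1.93 ± 0.34 and 1.94 ± 0.38). Monocyte-like cells also differed in Serp1 (2.53 ± 0.36, 4.3e-08), Fth1 (1.1 ± 0.19) and Itgb2 (1.86 ± 0.34), and macrophage-like cells in Lgals3bp (-2.43 ± 0.39), Bcl2a1b (3.81 ± 0.71) and Acp5 (2.00 ± 0.40). CD8+ cDC-like cells differed in Serpina3g (1.74 ± 0.31, 6.8e-05), Traf1 (2.26 ± 0.43), Lars2 (2.98 ± 0.62), Marcksl1 (2.72 ± 0.63) and Trafd1 (-2.15 ± 0.51). In pDC-like cells the difference was positive for Pld4 (17.8 to 24.6 against 8.32 to 1.86; 2.48 ± 0.34, 6.0e-09), Actb (1.30 ± 0.19), Srsf5 (3.23 ± 0.57), M34473 (2.87 ± 0.52) and Ptprc (1.78 ± 0.34). Without the filter on low counts the differences of V00821 (0.376), Ccr7 in mature dendritic-like (0.0573) and NK/T-like cells (0.0544), Itgb2 (0.102), Acp5 (0.0876), Serpina3g (0.0526), Traf1 (0.111), Marcksl1 (0.688) and Trafd1 (0.128) did not pass.

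By list, the NF-kB response was weaker than in CD8- cDC-like cells in mature dendritic-like cells (camera 0.000101; 2 of 12 genes lower) and stronger in macrophage-like cells (7.8e-05; 4 of 12 higher, 5 over the list alone). Costimulation genes responded less in mature dendritic-like cells (0.00179; 0 of 6 genes over all genes tested, 3 over the list alone), and so did class I genes (0.00179; 1 of 12, 2 over the list alone). Without called genes among the features, the mature dendritic-like class held 137 instead of 231 LPS cells. The CD8- cDC-like class held 416 instead of 296. Responses were not refitted in those classes, so any part due to cells changing class was not tested. The interferon response was weaker in macrophage-like cells (1.5e-05; 4 of 25 lower, 6 over the list alone). Other differences by list did not hold with an estimated correlation. Among these were interferon genes in pDC-like cells (0.000353, adjusted p = 0.0857 with an estimated correlation) and monocyte-like cells (0.0156, adjusted p = 0.247 with an estimated correlation), and NF-kB targets in B-like cells (0.0147, adjusted p = 0.0522 with an estimated correlation) and CD8+ cDC-like cells (0.0142, adjusted p = 0.0845 with an estimated correlation). Genes called were 22 in B-like (7 higher and 15 lower), 27 in mature dendritic-like (13 and 14), 34 in NK/T-like (26 and 8), 35 in monocyte-like (29 and 6), 45 in macrophage-like (23 and 22), 21 in CD8+ cDC-like (15 and 6) and 43 in pDC-like cells (39 and 4).

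The mixture of CD11c+ cells also shifted 2 hours after LPS. The shares of pDC-like and NK/T-like cells rose, and those of CD8- cDC-like, B-like, macrophage-like and CD8+ cDC-like cells fell. Since 81 of 500 features changed within a class, classes were also built without such genes, an alternative chosen after seeing the data. It is given as the last value of each pair. The share of pDC-like cells rose from 3.76 ± 1.40 to 14.1 ± 2.12% (10.3 points, exact two-sided adjusted p = 0.000414, 8 of 8 LPS libraries above all PBS; 10.2 points, 0.00124), and the share of NK/T-like cells from 8.40 ± 2.25 to 15.4 ± 2.06% (7.04 points, 0.000414, 8 of 8; 6.70 points, 0.00124). CD8- cDC-like cells fell from 37.6 ± 5.38 to 22.2 ± 2.93% (-15.5 points, 0.000414, 8 of 8; -9.08 points, 0.00547) and B-like cells from 21.7 ± 4.15 to 15.4 ± 3.10% (-6.30, 0.00518; -6.14, 0.00547; 0.105 with wells of at least 400 UMIs). Macrophage-like cells fell from 7.22 ± 2.30 to 4.37 ± 1.27% (-2.86, 0.00423; -2.99, 0.00787; -0.365, 0.745 at the lower resolution) and CD8+ cDC-like cells from 5.65 ± 1.76 to 3.49 ± 1.37% (-2.16, 0.0208; -3.41, 0.00547). Mature dendritic-like cells rose from 10.3 ± 2.24 to 17.4 ± 3.63% (7.06, 0.000932), but the difference was 1.44 points without called genes (0.231). Monocyte-like cells had 5.38 ± 1.68 and 7.72 ± 2.75% (2.34, 0.0595), and 3.32 points without called genes (0.0171).

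**Figure D3:**
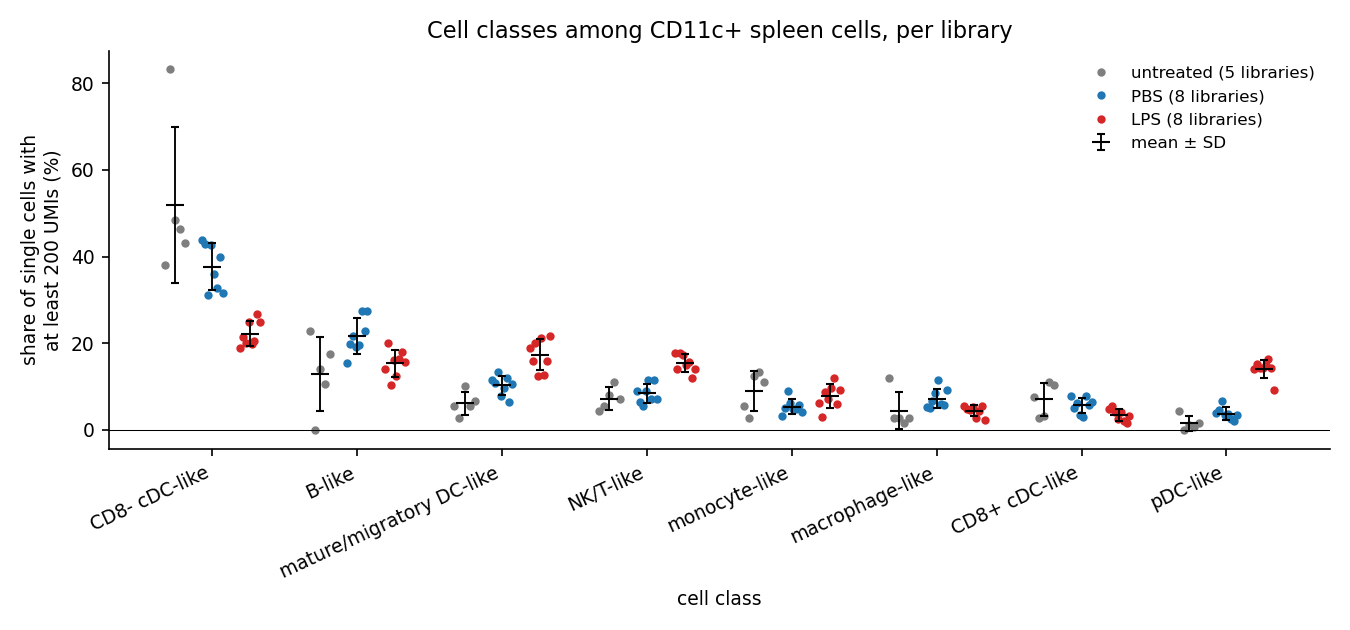
Percent of kept cells in each class, 1 point per library with mean ± SD, for untreated (n = 5), PBS (n = 8) and LPS (n = 8). The pDC-like points of LPS lie above all others.

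In each of 4 sequencing batches with 2 PBS and 2 LPS libraries, the directions were the same for every class except macrophage-like cells (3 of 4 lower). Differences within batches were 8.87 to 12.7 points for pDC-like, 3.80 to 10.3 for NK/T-like and -23.3 to -10.0 for CD8- cDC-like cells. As shares sum to 100, a rise of 1 class lowers the others. Shares of sorted cells give no cell numbers per spleen.

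Injection of PBS alone went with lower levels of a set of genes and with fewer increases. B2m, S100a4, Cox7b, Cox6c and Mrpl33 were lower after PBS than in untreated mice, and Cxcl10, Slpi and the macrophage genes Fcna and Slc40a1 were higher. PBS is the vehicle, so the comparison carries injection, handling, animal and sequencing run together: untreated and PBS libraries shared no sequencing batch, whereas PBS and LPS libraries did. Wells sorted with no cell held a median of 502 UMIs in untreated libraries (787.5 in 12 wells of replicate 2 and 88 in the 7 of the others) and 20.5 in PBS libraries. Of 1704 genes 38 rose and 114 fell (5 against 8 libraries), and 69 had all libraries apart. B2m fell from 77.3 ± 25.2 to 6.48 ± 1.92 (-3.58 ± 0.23, 5.5e-10), S100a4 from 36.0 ± 13.1 to 2.34 ± 1.44 (-3.92 ± 0.36, 7.1e-08), EF437368 from 34.0 ± 16.7 to 1.80 ± 1.12 (-4.22 ± 0.33, 1.1e-08) and Psmb7 from 2.89 to 0.149 (-4.34 ± 0.38, 4.3e-08). Gas5 (-3.82 ± 0.40), Mrpl33 (-3.79 ± 0.30), Cox7b (-3.72 ± 0.39) and Cox6c (-3.57 ± 0.36) fell as well, each with 8 of 8 PBS libraries below all untreated.

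Among increases, D17H6S56E-5 (0.465 to 1.77; 1.79 ± 0.29, 0.000120) was the only named gene with 8 of 8 PBS libraries above all untreated. Cxcl10 rose from 0.588 ± 0.387 to 3.02 ± 3.47 (2.56 ± 0.60, 0.00666; 7 of 8) and Slpi from 0.989 ± 0.547 to 6.02 ± 7.91 (2.67 ± 0.64, 0.00847; 6 of 8). Single PBS libraries carried part of both: the change of Cxcl10 was 1.78 without replicate 4 (0.00432) and that of Slpi 1.79 without replicate 5 (0.00443). Fcna (2.03 ± 0.54, 0.0171; 3 of 8), Slc40a1 (1.82 ± 0.50, 0.0208; 3 of 8) and Siglech (1.72 ± 0.49, 0.0271; 4 of 8) rose with the small nucleolar RNA entries Snord49a (2.68 ± 0.70, 0.0157; 6 of 8) and Snord15a (1.93 ± 0.52, 0.0182; 6 of 8). Fcna, Slc40a1, Siglech and Snord15a did not pass when untreated replicate 3, 4 or 5 was left out, nor Snord49a without replicate 4 or 5, with adjusted p up to 0.113. Under DESeq2 Fcna (0.104) and Snord49a (0.106) did not pass either. Without scaling factors the median of all genes moved by 0.13.

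No response list moved as a whole with PBS. Interferon genes had 0 higher and 1 lower of 14 (Ifitm3 -0.89 ± 0.20; camera 0.748), and cytokine genes 1 higher (Cxcl10) and 1 lower of 5 (Il1b -1.59 ± 0.29, 0.000450; camera 0.748). Immediate early genes had Klf2 higher (1.27 ± 0.25) and Hspa1b (-2.54 ± 0.37, 3.5e-05), Hspa1a (-2.18 ± 0.38) and Fos (-2.09 ± 0.42) lower of 7 (4 lower over the list alone; 0.0684). Class I genes had B2m and Tapbp (-1.15 ± 0.19) lower of 13 (1 higher and 3 lower over the list alone; 0.430), and class II genes H2-DMb2 higher of 12 (0.80 ± 0.22; 0.502). Ribosomal genes had 1 higher and 7 lower of 33 (8 lower over the list alone; Rpl26 -1.55 ± 0.28, Rps8 -1.62 ± 0.33; 0.294). No gene changed among 13 NF-kB targets (0.312), 3 interferon-gamma genes (0.748), 4 costimulation genes (0.430), 3 TLR4 genes (0.430), 4 glycolysis genes (0.748), 3 proliferation genes (0.502) or 2 glucocorticoid targets (1 higher over the list alone; 0.748). Markers of macrophages rose in 4 of 11 (C1qc, Slc40a1, Cd5l and Fcna) and of monocytes fell in 3 of 5 (Ly6c2, Lyz2 and Ms4a6c), with Faim3, Siglech and Ccr7 higher and Nkg7, Mpeg1, Clec4a1 and Cd209a lower.

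Class shares of PBS and untreated libraries differed by amounts that did not pass. CD8- cDC-like cells had 51.9 and 37.6% (-14.2 points, exact adjusted p = 0.0513), B-like 13.0 and 21.7% (8.71, 0.0513), mature dendritic-like 6.10 and 10.3% (4.19, 0.0513) and pDC-like 1.52 and 3.76% (2.24, 0.0513). Smaller differences were found for monocyte-like (-3.58, 0.113), macrophage-like (2.86, 0.194), CD8+ cDC-like (-1.36, 0.406) and NK/T-like cells (1.17, 0.406). With a library left out the CD8- cDC-like difference ranged from -17.7 to -6.37 points, and untreated replicate 2, with 83.3%, kept 36 cells. Its wells sorted with no cell held a median of 787.5 UMIs, beside 1035.5 in its wells of 1 cell, so its share may reflect RNA from other wells. With wells of at least 100 UMIs the 4 differences given first passed (each 0.0311). In classes built without called genes, chosen after seeing the data, the first 3 differences passed (-17.4 and 11.4 points, both 0.00622, and 4.18 points, 0.0166). That setting also made a cluster without a name, of 41 untreated and 8 PBS cells. It was counted with the main class that held most of its cells. The CD8- cDC-like class then held 353 untreated and 517 PBS cells, against 311 and 559 in the named cluster. The part of these differences due to this placement was not tested.

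Each gate sorted on surface proteins held mainly 1 class by RNA, in 61.8 to 100% of its cells, though not in every gate the class its sort names. Cells sorted as CD8+ CD317+ were pDC-like in 89 of 89 (lower limit 95.9%), with Siglech (33.5 per 10000), Klk1, Ly6d (60) and Bst2, the gene of CD317 (56.3). CD19+ cells were B-like in 48 of 48 B220+ (lower limit 92.6%) and 45 of 45 B220-negative cells (92.1%). In CD8+ CD86+ cells 61.8% were CD8+ cDC-like (50.9 to 71.9%, 89 cells) and 22.5% mature dendritic-like (14.3 to 32.6%), with Naaa at 33.2 (30.4 to 36.2), Ppt1 at 25.0, Cst3 at 261 and Cd86 at 1.05 (0.597 to 1.70). CD8-negative CD317+ cells were CD8- cDC-like in 90.7% (82.5 to 95.9%, 86 cells) and pDC-like in 9.30% (4.10 to 17.5%), with Cd209a at 15.2, Tppp3 at 10.4, Cd7 at 44.7 and Bst2 at 34.3. CD8-negative CD4+ ESAM+ cells were CD8- cDC-like in 81.5% (70.0 to 90.1%, 65 cells) and mature dendritic-like in 18.5% (9.92 to 30.0%), with Asb2 at 16.9, Ffar2 at 8.69, Cd4 at 3.57 and Esam at 1.34.

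The CD8+ CD86-negative gate was CD8- cDC-like in 88.0% (79.6 to 93.9%, 92 cells) and CD8+ cDC-like in 4.35%. It held 0 Cd8a UMIs (upper limit 0.322 per 10000), against 1.24 (0.747 to 1.94) in CD8+ CD86+ and 1.74 (1.07 to 2.65) in CD8+ CD317+ cells, and its well sorted with no cell held 6062 UMIs. Ccl17 (5.42) and Ccl22 (3.50) were its leading genes. NK1.1+ cells were NK/T-like in 84.6% (69.5 to 94.1%, 39 cells) and CD8- cDC-like in 12.8% (4.30 to 27.4%), with Gzma at 123, Ccl5 at 244 and Nkg7 at 35.5. Cells sorted as Gr1+ CD11b+ were placed as monocyte-like in 74.4% (57.9 to 87.0%, 39 cells), since no neutrophil class existed, but carried the neutrophil granule genes S100a9 (411), Ngp (129), Camp (97.4), Lcn2 (50.2) and Ltf (26.7). Another 20.5% of the Gr1+ CD11b+ cells (9.30 to 36.5%) were placed as CD8- cDC-like. No cell was left without a class, so the CD8- cDC-like class can hold cells of other types. Granule genes were also present in CD19+ B220+ cells (Mpo 14.6, Prtn3 12.9) beside Cd79b (24.9) and Ms4a1 (11.0), and the B220-negative gate held immunoglobulin entries (M34473 646, M13680 607, abParts 529). Itgax, the gene of CD11c, was 4.46 to 8.69 in the 5 CD11c+ gates and 0 to 4.14 in the other 4. Each gate had 1 library, so these differences have no test.

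**Figure D4:**
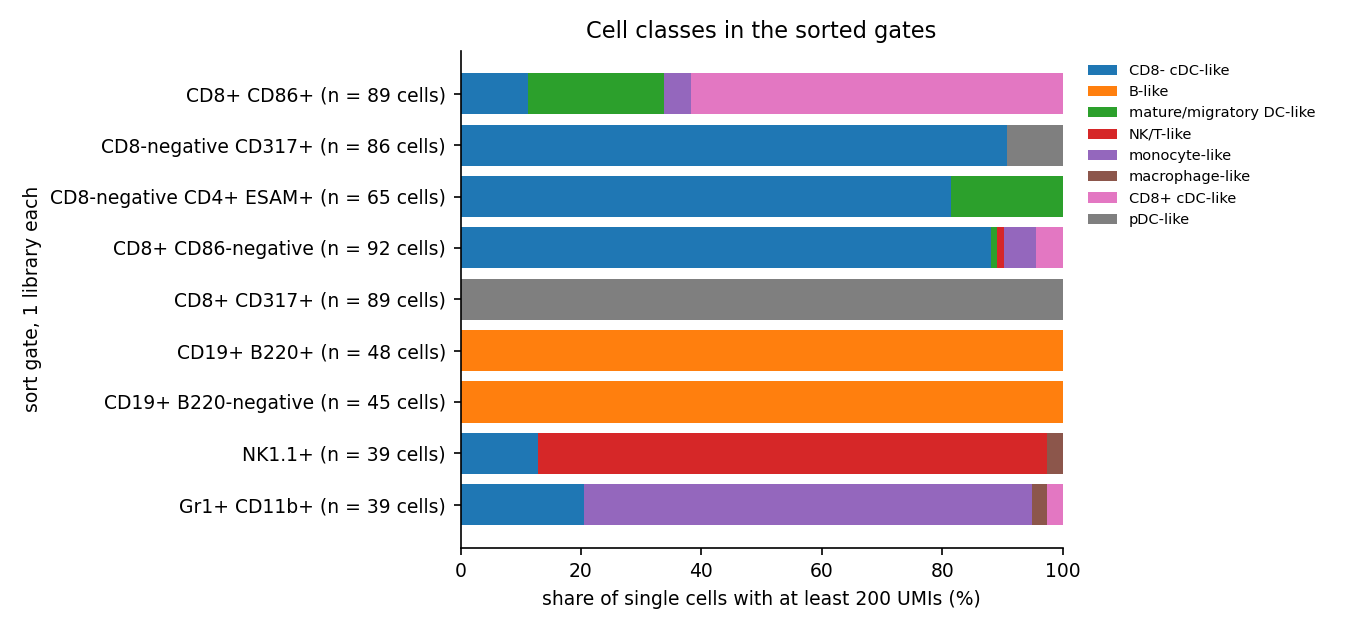
Percent of cells of each class in 9 sorted gates, as stacked horizontal bars with 1 library per gate. CD8+ CD317+ and both CD19+ gates hold a single class.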

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

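The tests by other splits of the libraries, the number of mice, the sequencing batches held in common, the classes built without called genes, the pDC-like share outside the CD8- cDC-like class, the comparison of transcript lengths, and the Cxcl10 values of classes other than NK/T-like were tests chosen after the result was seen, and the other tests were written down before.

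Cxcl10 was higher after LPS in all 8 classes, including NK/T-like and B-like cells. RNA carried over from other wells is argued against in all but B-like cells by the LPS wells sorted with no cell, whose Cxcl10 UMIs per well were at most 0.0743 of the mean of NK/T-like wells and at most 0.183 of that of the other 6 classes. A second cell in some wells is argued against there too, since 93.1% of 204 NK/T-like wells (88.8 to 96.2%) and at least 83.2% in the other 6 classes held a Cxcl10 UMI. In B-like cells the ratio was 0.105 with an upper limit of 0.582, and 57.4% of wells held a Cxcl10 UMI (39.7% thinned to 200 UMIs), so both explanations cannot be told apart from a rise in B-like cells, with too few wells without a cell. Wells sorted with no cell cannot show RNA that entered a well together with the sorted cell. That source was not tested in any class. The well table gives 1 mouse per treatment, so a difference between the 2 mice other than LPS cannot be told apart from LPS.

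The shares of pDC-like and mature dendritic-like cells were higher after LPS. Assignment by genes that LPS changes is argued against for pDC-like cells, whose difference was 10.2 points in classes built without the called genes. For mature dendritic-like cells the difference was 1.44 points there, as such assignment predicts. Of the 10 leading genes of the class, 5 were called genes. Of these, Gadd45b was outside the features of the main setting too. Leaving out the others could also lower the difference through a poorer definition of the class. Fewer CD8- cDC-like cells in the sort would raise the other shares alike, yet outside that class the pDC-like share rose by 12.0 points (6.04 ± 2.09 to 18.1 ± 2.56%, exact p = 0.000155) while B-like cells went from 34.6 to 19.8% and macrophage-like cells from 11.6 to 5.62%. Entry of pDC into the spleen, loss of other CD11c+ cells and a higher surface CD11c on pDC after LPS stay open and were not tested. So does a difference between the mice, with 1 mouse per treatment, which cannot be told apart from LPS.

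The genes lower in PBS than in untreated libraries included the abundant B2m and S100a4. In CD8- cDC-like cells their median log2 ratio to untreated was -0.043 in the 2 CD8-negative gates (quartiles -0.54 to 0.27) and -1.20 after PBS, which is consistent with an effect of the injection; all cells of the 9 gates, some of other cell types, had medians of -0.96 to -0.065. Transcript length as the whole cause is argued against for genes within the length quartiles of the set (637 to 1329). All 748 tested genes of that range, called or not, lay only 0.076 below the 537 longer ones (difference -0.076, limits -0.13 to -0.0083). The set itself, picked for being lower, had a median of -1.56. That 47 of the 748 were called lower follows from the choice of the range. The shortest genes of the set lay outside the range and were not tested. Lower genes were shorter, with a median length of 783 against 965.5 in genes not called (lengths were found for 94 of the 114). A difference between sequencing batches or mice stays open: 0 batches held both groups, so it cannot be told apart from the injection.

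For each count of genes, 1 of 100 splits of the libraries, the real one, gave as many genes. This argues against a chance split of the libraries. It cannot exclude a chance difference between animals, since the PBS libraries came from 1 mouse and the LPS libraries from 1 mouse. The real value and the highest other were 927 and 3 for all cells, 292 and 124 for CD8- cDC-like, 43 and 24 for B-like, 63 and 2 for mature dendritic-like, 39 and 14 for NK/T-like, 40 and 11 for monocyte-like, 27 and 16 for macrophage-like, 31 and 13 for CD8+ cDC-like, 85 and 2 for pDC-like cells, and 152 and 34 for PBS against untreated. For the difference of the LPS response from that of CD8- cDC-like cells, picked out because the classes differed, they were 22 and 13 in B-like, 27 and 6 in mature dendritic-like, 34 and 3 in NK/T-like, 35 and 7 in monocyte-like, 45 and 7 in macrophage-like, 21 and 3 in CD8+ cDC-like and 43 and 10 in pDC-like cells.

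Libraries far from the others of their group were found 18 times in 109 groups of values examined. About 1 in 20 would be picked by chance if the values were independent. Many of the 18 were interferon genes of 1 library, so their number does not measure an excess. PBS replicate 4 held the most UMIs per kept cell (median 750.5; others 456 to 584). The same library was high in interferon genes: Cxcl10 at 11.7 (others 0.644 to 4.02; 11.3 against 0.624 to 3.90 in the fit with untreated libraries), Ifit1 at 2.54 (0.107 to 0.543), Oasl1 at 1.67 (0.0852 to 0.610), Rsad2 at 1.23 (0 to 0.493), Ifit2 at 1.01 (0 to 0.370), Mx2 at 0.652 (0 to 0.256) and I830012O16Rik at 0.507 (0 to 0.213). Mt2 was 0.580 (0 to 0.129) and Fam105a 4.35 (2.13 to 3.09) there. Cxcl11 was 0.242 in PBS replicate 7 and 0 in the others, Slpi was 25.2 in PBS replicate 5 (0.719 to 5.20), and EF437368 was 4.29 in PBS replicate 6 (0.874 to 2.28). Slc40a1 was 2.76 in untreated replicate 1 (0.143 to 0.605), where macrophage-like cells made up 12.0% (others 1.66 to 2.78%). CD8- cDC-like cells made up 83.3% of untreated replicate 2 (38.0 to 48.4%), which kept 36 cells, and pDC-like cells 9.19% of LPS replicate 8 (14.0 to 16.3%).

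Signals were also present in wells used in no comparison. In untreated replicate 2, 48 wells sorted with 2 to 32 cells held a median of 2037.5 UMIs (0 to 56801), against 787.5 in its 12 wells with no cell. In the batch of the CD19+ gates, 30 wells of 100 or 1000 cells held a median of 180124, against 94. In the batch of the NK1.1+ and Gr1+ gates, 47 wells of single splenocytes without a sort marker held a median of 357, against 62, and of 40 kept 23 were B-like (57.5%, 40.9 to 73.0%), 9 CD8- cDC-like (22.5%), 6 NK/T-like (15.0%) and 2 macrophage-like (5.0%).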

How the results depend on the processing

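Classes built without called genes, the block within classes, library totals with no scaling factor and the libraries left out of the PBS against untreated shares were tests chosen after the result was seen. No named gene reversed its direction under any setting run. Named genes kept their side of the threshold in 991 values over other settings and in 1637 with a library left out, and lost it in 33 and 32: Gnai2 was lost in 19 settings (highest adjusted p 0.262), Psap in 6, Fcna and Siglech in 4 each, and Slc40a1, Snord15a and Snord49a of the PBS comparison in 3 each. Without the filter on low counts 22 named genes were lost, a setting that changes the genes tested and the scaling together. It was the only alternative under which the differences between classes were refitted. Counts of genes stayed within 1.5-fold in 84 values and moved by more in 19. With a library left out they ranged over 879 to 974 (all cells), 267 to 332 (CD8- cDC-like), 35 to 56 (B-like), 50 to 84 (mature dendritic-like), 30 to 65 (NK/T-like, 65 without PBS replicate 2), 30 to 42 (monocyte-like), 25 to 33 (macrophage-like), 21 to 37 (CD8+ cDC-like), 78 to 106 (pDC-like) and 111 to 199 (PBS against untreated). With the sequencing batch as a block 497 genes rose and 525 fell in all cells, and within each of the 4 batches alone 369 to 436 rose and 182 to 223 fell. Of the gates, all 18 shares and 284 gene levels held, and 4 levels moved. Small changes could be missed: changes of 1.5-fold were recovered on simulated data in 38.8% of genes for all cells and 8.96% for PBS against untreated. Sums of at least 10 cells left too few libraries in 4 classes. No paired analysis was possible because no label ties a single PBS library to a single LPS library, so the sequencing batch, with 2 of each, was the only block used. Sums per mouse were not run, since each treatment had 1 mouse.

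Without the low count filter, which lets many sparse genes into the test and the scaling, called genes were 1947 in all cells (1217 higher, 730 lower), 991 in CD8- cDC-like, 151 in B-like, 394 in mature dendritic-like, 297 in NK/T-like, 279 in monocyte-like, 99 in macrophage-like, 193 in CD8+ cDC-like and 318 in pDC-like cells, and 397 for PBS against untreated. Called lower genes with a fold above 0 there numbered 3 in mature dendritic-like, 3 in NK/T-like and 12 in pDC-like cells, and the median of all genes moved by -0.25 in B-like, 0.49 in mature dendritic-like, 0.59 in NK/T-like and -0.28 in macrophage-like cells. Differences from the CD8- cDC-like response were 12 in B-like, 16 in mature dendritic-like, 14 in monocyte-like, 20 in macrophage-like, 4 in CD8+ cDC-like and 78 in pDC-like cells. With wells of at least 400 UMIs 13 genes were called in B-like and 70 in monocyte-like cells, and at the lower resolution 70 in macrophage-like cells; the cause was not tested.

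With an estimated correlation camera no longer passed for 24 lists. These were class II (0.143) and ribosomal genes (0.557) in all cells, and NF-kB (0.355), costimulation (0.118), class II (0.342) and ribosomal genes (0.490) in CD8- cDC-like cells. Ribosomal genes in NK/T-like (0.389) and monocyte-like cells (0.137), interferon genes in monocyte-like cells (0.0588), NF-kB targets in macrophage-like cells (0.117), and interferon-gamma, class II and ribosomal genes in pDC-like cells (each 0.195) were lost too. Among differences from the CD8- cDC-like response the lost lists were cytokines (0.0522), NF-kB (0.0522) and ribosomal genes (0.422) for B-like, class II (0.331) and ribosomal (0.164) for mature dendritic-like, interferon (0.247), class II and ribosomal (0.328 each) for monocyte-like, NF-kB and costimulation (0.0845 each) for CD8+ cDC-like and interferon genes (0.0857) for pDC-like cells.

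Of the shares, the B-like difference after LPS was -3.59 points (adjusted p = 0.105) with wells of at least 400 UMIs, the mature dendritic-like difference 1.44 (0.231) without called genes, and the macrophage-like difference -0.365 (0.745) at the lower resolution. The monocyte-like difference passed with response lists kept (2.53, 0.0288), at the higher resolution (2.49, 0.0472) and without called genes (3.32, 0.0171). PBS against untreated passed with wells of at least 100 UMIs for CD8- cDC-like (-15.4), B-like (9.46), mature dendritic-like (3.94) and pDC-like cells (2.32; all 0.0311), and without called genes for the first 3 (-17.4, 11.4 and 4.18). With a library left out these 4 ranged over -17.7 to -6.37, 5.47 to 11.2, 3.36 to 5.22 and 1.82 to 2.95 points (monocyte-like -5.12 to -2.50, macrophage-like 2.19 to 4.76), and calls changed without untreated replicates 1 or 3 or PBS replicates 1 or 7. The cause was not tested. Without called genes, an unnamed cluster of 41 untreated and 8 PBS cells was counted in a named class.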

Other observations

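The values of this part were chosen after they were seen, and no test was run on them. Several cytokine genes too sparse for the comparisons moved with LPS in raw UMIs over all kept PBS and LPS cells (774523 and 996337 UMIs). Il27 went from 9 UMIs in 8 cells to 135 in 93 cells, of which 25 were CD8+ cDC-like, while Il12b went from 24 to 7. Tnf had 25 UMIs in 20 cells after PBS and 134 in 90 cells after LPS, 21 of them macrophage-like, and Il18 had 45 and 82. Ifnb1, the gene of interferon beta, had 0 UMIs in both, although its target genes rose. Il6 had 1 and 15 UMIs, Ccl2 0 and 12, and Lcn2 0 and 33, the last in 22 cells of which 18 were monocyte-like. Among sensors Tlr4 had 6 and 1 UMIs, Tlr2 33 and 122 (102 cells) and Traf6 4 and 27. The glycolysis entry genes Hk2 (12 and 53) and Slc2a1 (27 and 50) went up in number while the enzymes Gpi1 and Aldoa fell. Mmp9 went from 17 to 0. Globin genes were seen in more cells, with Hba-a2 at 31 and 381 UMIs (35 cells after LPS) and Hbb-b1 at 20 and 252 (20 cells).

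Granule genes of myeloid precursors appeared in wells sorted as CD19+. Mpo was 14.6 per 10000 (11.4 to 18.5) in B220+ cells, where 19 of 48 wells held it, and 7.52 in B220-negative cells (18 of 45 wells). Prtn3 was 12.9 and 4.78, Elane 6.24 and 3.42, and Ctsg 3.87 and 1.91. In wells of 100 or 1000 cells of the same batch Mpo was 4.04, Prtn3 3.78, Elane 2.63 and Ctsg 2.71. B-like cells of untreated and PBS libraries held 0 Mpo UMIs in 227994 (upper limit 0.162).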
